A study of Homo sapiens with 20 samples.

How the data were processed

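Messenger RNA of AGS cells was sequenced in 20 libraries of 6 groups: WT, R and KO, each untreated or treated with 1 µM BYL719 for 24 hours. WT had 3 libraries per condition, R 1 library from each of 3 clones and KO 2 libraries from each of 2 clones. Per the labels, cells were grown in DMEM/F-12K with 10% serum and RNA was extracted with a column kit. The codes of the clones in the deposited files could not be matched to the clone numbers of the labels, so the file codes are used.

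Per the labels, the authors aligned reads to hg38 with HISAT2 and tested genes with DESeq2 (DESeq is also named), with no versions given. The program that counted reads, the annotation release and the strand setting are not stated. The authors deposited 9 tables, 1 per comparison, with the raw count of each gene in each library, a log2 ratio of the first group over the second, a raw p-value and an adjusted p-value, per the file headers. A gene was listed in a table where its reads over that table's libraries totalled 2 or more. The tables held 23750 to 25203 genes, 28495 in any of them, and 0 counts differed between tables for the same library. Only the deposited counts were used for the tests below, and the authors' log2 ratios and p-values served as a comparison.

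Total counts ranged from 14484765 to 19289368 with a median of 15124013, and the highest was an untreated WT library. The 10 genes with the most counts held 4.20% to 6.43% of a library and mitochondrially encoded genes 1.19% to 5.90%. A group with no counts of a gene was compared at a floor of 3 counts over the group, and a group with 1 to 3 counts by a ratio with its 95% counting interval.

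Counts were normalized by TMM and filtered with filterByExpr, and each of the 9 comparisons was fitted by itself with the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Differences between drug responses were tested as interaction contrasts over 2 lines. SEs were derived as the size of the log2 fold change over the square root of the F statistic. They can be too small for genes with few counts in a group. The 33 gene lists held 743 genes, written down from general knowledge, of which 714 matched a listed gene and 29 did not. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry. Figures and tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

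The design and the alternatives were fixed before the data were examined. The alternatives were DESeq2 scaling, the Wald test of DESeq2 1.42.0, limma-voom, no filter, a mean of 50 or more counts, protein-coding genes only, all 6 groups in 1 fit, a fold of 2 or more, the replicate or clone as a block, the clones summed or alone, and each library left out. List tests with the clone as a block, with each KO clone alone and of the interactions, and the counts of genes changed in 2 or 3 lines, were added after the data were seen. The test of long chromosome blocks was also chosen after the data were seen. It first used 1 bound for windows of every size, which gave 3 windows, and after that result was seen the bound was changed to scale with the number of genes in a window and the tests were rerun.

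In R and KO the deviations of libraries from their group means were compared between treatments. Libraries of the same clone deviated together, with correlations of 0.25, 0.32 and 0.48 in R and of 0.22 to 0.37 in KO, against -0.20 to -0.36 between the KO clones. The clone therefore pairs these libraries, per the codes in the deposited files, and fits with the clone as a replicate block are given where they move a result.

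The named genes followed a rule. It took CBFB, RUNX1, RUNX2, RUNX3, PIM1, PIM2, PIM3 and PIK3CA, and the 10 largest rises and 10 largest falls among called protein-coding genes with a mean of 100 or more normalized counts and no overlap between the groups. For KO against R and for the treated comparisons between lines it took 5 and 5. It further took up to 4 called members of each list with the smallest adjusted p, and the 10 genes with the smallest interaction p. The text names part of these, and the genes named for shared drug responses, the neighbours of GLB1 and the genes low in both R and KO were chosen after their values were seen.

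The fits were tested on simulated data with 100 genes changed per fold size. For the drug in WT, 85.0% of 1.5-fold and 99.0% of 2-fold changes were recovered, with 8 false calls among 192. For untreated R against WT the shares were 59.0% and 95.0% (16 of 170), for untreated KO against WT 77.0% and 99.0% (8 of 184), and for the drug in KO 75.0% and 96.0% (11 of 182). A 2-fold difference between responses was recovered in 79.5% of 200 genes for R and WT and in 85.5% for KO and WT. A list of 22 genes raised 1.4-fold was called in 10 of 10 simulated sets and 0 of 320 other lists were. Genes and libraries were drawn independently in these simulations. They therefore do not show how often lists of correlated genes, or libraries paired by clone, give false calls. The overlap of R and KO was compared with simulated unchanged groups that share simulated WT libraries. Duplicate symbols were kept apart by identifier, and no library was left out. Pairs of libraries of a group had a chi-square per degree of freedom of 2.53 to 30.39, over genes with 20 or more reads. The highest was between untreated KOB2_1 and KOD2_2. Untreated WT 3 stood at 18.11 and 15.87 from untreated WT 1 and 2, which stood at 2.53 from each other.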

Results

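The transcriptome of AGS cells, a human gastric adenocarcinoma line, was measured by RNA sequencing in 20 libraries from 6 groups. Parental cells (WT), clones resistant to BYL719 (R) and clones with a knockout of CBFB (KO) were each sequenced untreated and after 24 hours in 1 µM BYL719, an inhibitor of the PI3Kα catalytic subunit. WT had 3 libraries in each condition and R had 1 library from each of 3 clones (RC6, RD4 and RD5). KO had 4 libraries in each condition, 2 from each of 2 clones (KOB2 and KOD2). Total counts per library ranged from 14484765 to 19289368. Levels are TMM-normalized CPM, given as mean ± SD. Each log2 fold change is followed by an SE derived from the F statistic of the edgeR fit. That SE can be too small where a group has few counts. The ranges given for genes with 0 to 3 counts in a group cover counting error only. The largest rises and falls are ranked among called protein-coding genes with a mean of 100 or more normalized counts and no overlap between the groups.

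CBFB encodes CBFβ, the partner subunit that stabilises the DNA binding of RUNX transcription factors. The first question was how far its transcript differed in the lines. The gene (ENSG00000067955, hg38 chromosome 16, 67029116 to 67101058) stood at 221.4, 225.4 and 209.6 CPM in the untreated WT libraries and at 216.3, 187.7 and 223.7 CPM in the treated ones. In KO it was at 88.25 and 93.24 CPM in untreated KOB2, 64.09 and 66.14 in untreated KOD2, 131.7 and 116.2 in treated KOB2, and 65.92 and 66.18 in treated KOD2. In R it was at 123.8, 139.4 and 143.4 CPM untreated and at 146.3, 150.6 and 157.6 CPM treated (RC6, RD4 and RD5). Against WT, CBFB was lower in untreated KO (log2 fold change -1.47 ± 0.13, adjusted p = 6.9e-06) and in untreated R (-0.69 ± 0.08, adjusted p = 1.3e-04). Under drug it was lower in KO (-1.10 ± 0.21, adjusted p = 0.0025) and in R (-0.46 ± 0.08, adjusted p = 8.2e-04, which became 0.065 with all 6 groups in 1 fit). With the drug CBFB stood 0.18 ± 0.07 higher in R (adjusted p = 0.22, and 0.012 with the clone as a replicate block). Gene totals cover the whole transcript, so these counts say how much CBFB RNA was left and not whether it encoded protein.

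RUNX1 (ENSG00000159216, chromosome 21, 34787801 to 36004667), a DNA-binding partner of CBFβ, moved in opposite directions in R and KO. Its level was 163.7 ± 18.4 CPM in untreated WT (n = 3), 92.21 ± 23.1 in untreated R (n = 3) and 331.0 ± 21.5 in untreated KO (n = 4). RUNX1 was lower in R than in WT (log2 fold change -0.83 ± 0.17, adjusted p = 0.0028) and higher in KO (1.04 ± 0.09, adjusted p = 9.5e-06). Its drug response in KO was 0.19 ± 0.07 (adjusted p = 0.074, and 0.03 with the clone as a replicate block). With each clone's libraries summed that response was not called. RUNX2 and RUNX3, the other partners, had 13 and 2 counts or fewer in every WT and R library. In KO their counts split by clone: KOB2 libraries held 25 to 56 counts of RUNX2 and 16 to 20 of RUNX3, and KOD2 libraries 0 to 6 of RUNX2 and 0 of RUNX3.

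PIM1 (ENSG00000137193, chromosome 6, 37170203 to 37175426), a serine/threonine kinase of cell survival and growth, was higher in both R and KO than in WT. It rose with the drug in WT from 59.31 ± 2.02 to 98.60 ± 3.52 CPM (n = 3 and 3, log2 fold change 0.74 ± 0.08, adjusted p = 7.8e-05). In KO it rose from 94.25 ± 11.7 to 179.3 ± 27.6 CPM (n = 4 and 4, 0.93 ± 0.12, adjusted p = 3.3e-04, which became 0.096 with each clone's libraries summed). In R the means were 100.2 ± 18.6 untreated and 141.1 ± 25.2 treated (n = 3 and 3), a log2 fold change of 0.51 ± 0.16 with an adjusted p of 0.12. That p was 1.8e-06 with the clone as a replicate block, 0.021 with DESeq2, 0.038 without a filter, 0.041 with all 6 groups in 1 fit and 0.044 without untreated RD5. The response did not differ detectably between R and WT (difference -0.23, adjusted p = 0.8), KO and WT (0.21, adjusted p = 0.63) or KO and R (0.43, adjusted p = 0.39, and 0.016 with the clone nested in the line). Before treatment PIM1 exceeded WT by 0.76 ± 0.12 in R (adjusted p = 7.9e-04) and by 0.69 ± 0.10 in KO (adjusted p = 2.9e-04). Under drug the excess was 0.52 ± 0.11 in R (adjusted p = 0.0025) and 0.90 ± 0.11 in KO (adjusted p = 7.6e-05). PIM2 and PIM3, the sister kinases, did not pass the test for the drug in any line, with log2 fold changes from -0.20 to 0.17, except that PIM3 passed in WT without untreated library 3 (0.24, adjusted p = 0.03).

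**Figure D1:**
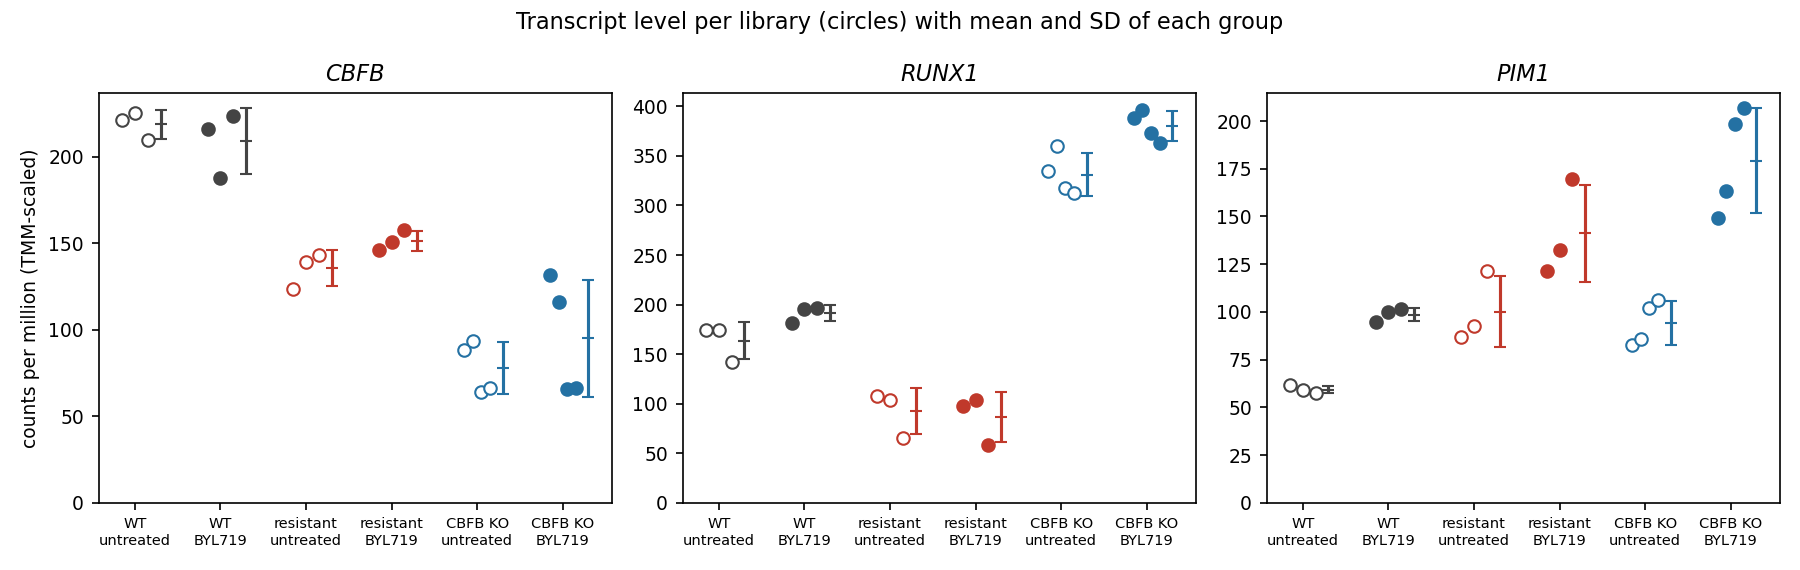
Levels of CBFB, RUNX1 and PIM1 in CPM (vertical axes, linear, from 0) in each of the 20 libraries (points) of the 6 groups, with the mean and SD as bars. Untreated CBFB averaged 218.8 in WT, 135.6 in R and 77.93 in KO, and the treated KO points separate by clone.

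What did the drug change in parental cells? In WT the amino acid and lipid synthesis programmes fell, while interferon-stimulated genes and targets of FOXO factors rose. Of 20 measured targets of ATF4, the factor that drives amino acid synthesis and uptake under stress, 16 fell and 1 rose (18 passed when adjusted over the list alone; camera adjusted p = 2.4e-27, and 0.019 with an estimated correlation). PSAT1 (ENSG00000135069), an enzyme of serine synthesis, dropped from 266.5 ± 6.45 to 78.29 ± 2.90 CPM (log2 fold change -1.76 ± 0.08, adjusted p = 3.7e-08). PSPH, the last enzyme of that pathway, changed by -1.52 ± 0.10, the glutathione-degrading enzyme CHAC1 by -1.73 ± 0.13 and the cystine transporter SLC7A11 by -1.96 ± 0.18. Of 27 SREBP targets of sterol and fatty acid synthesis, 18 fell and 0 rose (19 adjusted over the list alone; adjusted p = 3.3e-14, and 0.045 with an estimated correlation). Examples were the sterol enzyme DHCR7 (-0.74 ± 0.08), INSIG1 (-0.94 ± 0.11) and the desaturase SCD (-0.85 ± 0.10).

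Of the interferon-stimulated genes in WT, 25 of 31 rose and 0 fell (26 adjusted over the list alone; adjusted p = 8.7e-34, and 0.017 with an estimated correlation). They included the antiviral genes OAS2 (1.49 ± 0.10), MX2 (1.71 ± 0.11), IFIT3 (1.36 ± 0.10) and IFIT1 (1.07 ± 0.09). Among 21 FOXO targets that rise when PI3K signalling is low, 12 rose and 1 fell (15 adjusted over the list alone; adjusted p = 4.2e-09, and adjusted p = 0.083 with an estimated correlation). The ubiquitin ligase gene FBXO32 rose by 1.25 ± 0.18, YPEL3 by 1.04 ± 0.10, CITED2 by 0.79 ± 0.10 and KLF6 by 0.74 ± 0.09. Receptor tyrosine kinases and ligands had 9 of 21 higher and 1 lower (18 adjusted over the list alone; adjusted p = 0.0036, and adjusted p = 0.21 with an estimated correlation), among them the insulin receptor INSR (0.75 ± 0.13), FGFR3 (0.60 ± 0.09) and ERBB3 (0.52 ± 0.09). Of 28 genes of the G1 to S transition 11 rose and 0 fell (15 adjusted over the list alone; adjusted p = 2.3e-06, and 0.039 with an estimated correlation), among them cyclin D1 (CCND1, 0.75 ± 0.07). In the list of 28 mitotic genes, edgeR called 0 higher and 0 lower (0 adjusted over the list alone, camera adjusted p = 0.4, median 0.05). Mitochondrially encoded genes had 9 of 13 lower and 0 higher (12 adjusted over the list alone; adjusted p = 1.8e-08, and adjusted p = 0.18 with an estimated correlation). The mitochondrial share of counts was 2.13% to 2.40% in untreated and 1.34% to 2.04% in treated WT libraries.

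Among single genes in WT, the largest rises with the drug were the matrix gene FBLN2 (2.70 ± 0.15), C6orf222 (2.61 ± 0.19), the adhesion glycoprotein gene CEACAM5 (2.45 ± 0.15, from 5.893 ± 1.08 to 32.31 ± 4.82 CPM) and the metallothionein MT2A (2.28 ± 0.12). RETREG1 of endoplasmic reticulum turnover (1.91 ± 0.10), APOL1 (1.89 ± 0.09), LY6G6C (1.82 ± 0.17), MX2 (1.71 ± 0.11) and the pro-apoptotic gene BMF (1.67 ± 0.10) followed. Besides the ATF4 targets above, the largest falls were the fibrinogen chains FGG (-2.79 ± 0.15) and FGA (-2.03 ± 0.13), the mTORC1 inhibitor gene DDIT4 (-2.05 ± 0.26) and the stemness factor SOX2 (-1.64 ± 0.14). SMN1 (-1.49 ± 0.17) and PSG11 (-1.37 ± 0.15) are uncertain because reads of near-identical genes cannot be assigned with certainty, and the call of SMN1 ended with all 6 groups in 1 fit (adjusted p = 0.055). PIK3CA, which encodes the drug's target, changed by 0.42 ± 0.13 (adjusted p = 0.041), a call that ended with all 6 groups in 1 fit (0.051) and without untreated library 2 (0.11) or 3 (0.071) or treated library 1 (0.12), 2 (0.05) or 3 (0.17). In all, 1761 of 13698 genes changed, 1003 higher and 758 lower, and 217 of them at least 2-fold. The count was 923 without treated library 3, 997 without treated library 1 and 1113 without untreated library 2.

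**Figure D2:**
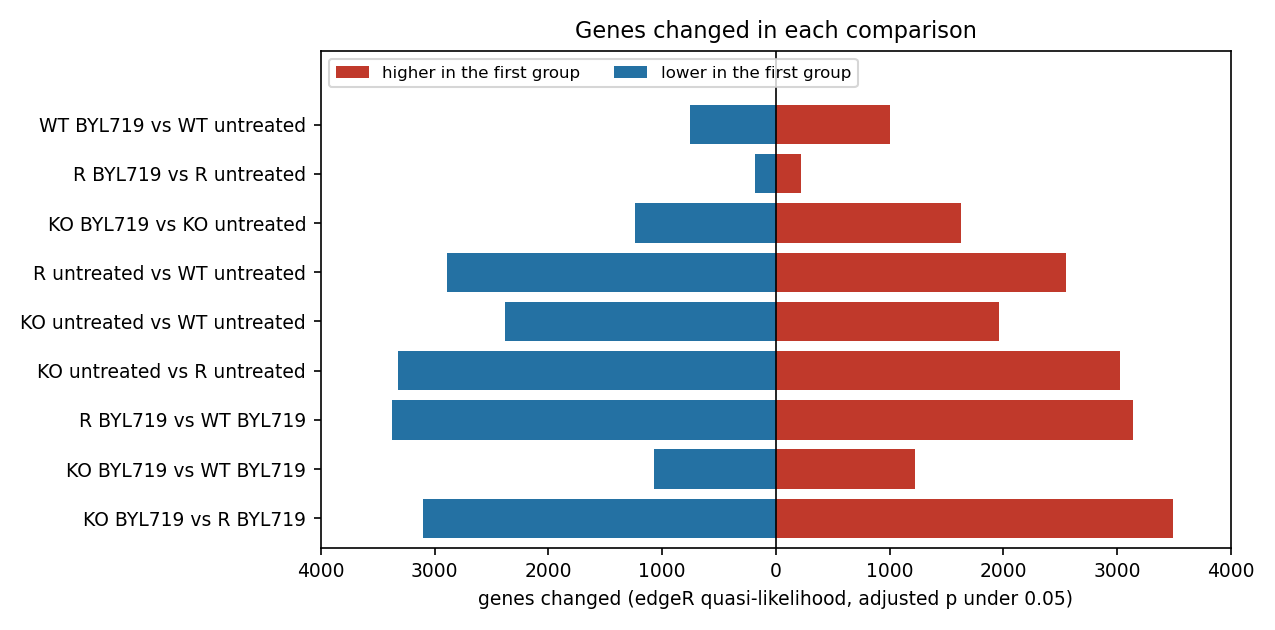
Genes higher and lower (horizontal axis, number of genes at adjusted p under 0.05, bars from 0) in each of the 9 comparisons (vertical axis). The drug changed 1761 genes in WT, 405 in R and 2870 in KO.

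The resistant clones were asked the same question. In R the ATF4 and SREBP lists also fell with the drug at the preset correlation. In the fit without a clone block, fewer of their members passed the threshold than in WT. Of 20 ATF4 targets 7 fell and 0 rose (13 adjusted over the list alone; adjusted p = 3.4e-10, and adjusted p = 0.059 with an estimated correlation), including PSAT1 (-0.89 ± 0.09) and CHAC1 (-1.11 ± 0.17). Of 27 SREBP targets 4 fell and 0 rose (20 adjusted over the list alone; adjusted p = 1.5e-09, and adjusted p = 0.42 with an estimated correlation), among them DHCR7 (-0.59 ± 0.08) and the citrate-cleaving enzyme ACLY (-0.41 ± 0.06). FOXO targets had 4 of 21 higher and 0 lower (6 adjusted over the list alone; adjusted p = 4.1e-04, and adjusted p = 0.42 with an estimated correlation), among them ERBB3 (0.83 ± 0.11), KLF6 (0.60 ± 0.09) and the cell cycle inhibitor CDKN1B (0.39 ± 0.06). Of 23 p53 targets 4 fell and 0 rose (11 adjusted over the list alone; adjusted p = 6.5e-08, and adjusted p = 0.21 with an estimated correlation), led by MDM2, the ligase that degrades p53 (-0.52 ± 0.06). Interferon-stimulated genes had 0 of 28 called by edgeR (0 adjusted over the list alone), with a median of 0.22 and a camera adjusted p of 0.079. With the clone as a replicate block 6 of them rose and 0 fell (camera adjusted p = 0.011, and adjusted p = 0.53 with an estimated correlation). That block also raised the falls to 13 ATF4, 20 SREBP and 14 p53 targets, each with 1 rise, and turned the FOXO targets into 10 higher and 3 lower. The estimated-correlation adjusted p was then 0.24 for the ATF4 targets.

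The largest rises in R were MT2A (2.60 ± 0.27), the calcium channel subunit gene CACNG6 (2.35 ± 0.19), MEGF6 (2.32 ± 0.25), LY6G6C (1.94 ± 0.30) and CEACAM5 (1.76 ± 0.19). HR (1.71 ± 0.22), the hyaluronan-degrading CEMIP (1.69 ± 0.18) and the membrane protein gene EMP1 (1.64 ± 0.17) followed. The lipid transporter ABCA12 (-1.51 ± 0.18), the endocytic receptor LRP2 (-1.46 ± 0.20), TP53INP2 (-1.41 ± 0.29) and SOX2 (-1.15 ± 0.16) fell the most. CKMT1B (-1.05 ± 0.22) shares reads with a near-identical copy and is uncertain. In total 405 of 13576 genes changed, 219 higher and 186 lower, and 2850 had an unadjusted p under 0.05. This count rested on the treatment of the clones: with the clone as a replicate block it was 3412 (1758 higher and 1654 lower), and all 405 were among them. DESeq2 called 920, the fit of all 6 groups 772, and the fit without a filter 643, of which 48.7% were higher against 54.1%. Leaving out 1 library gave 21 without treated RC6, 27 without untreated RD4, 35 without untreated RC6, 39 without treated RD4 and 214 without treated RD5. Of the 10 largest rises and 10 largest falls in R, only MT2A (highest adjusted p = 0.047) and CACNG6 (0.034) passed whichever single library was left out.

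In the CBFB knockout, the drug lowered ribosome biogenesis and raised FOXO targets, immediate early genes and TGFβ pathway genes. Of 28 MYC targets of ribosome biogenesis, 26 fell and 0 rose (26 adjusted over the list alone; adjusted p = 2.6e-25, and adjusted p = 0.083 with an estimated correlation). Examples were the nucleolar genes MYBBP1A (-0.88 ± 0.10), DDX21 (-0.69 ± 0.09) and NOLC1 (-0.59 ± 0.08) and the RNA polymerase I subunit POLR1B (-0.61 ± 0.07). FOXO targets had 17 of 22 higher and 0 lower (17 adjusted over the list alone; adjusted p = 6.1e-13, and 0.048 with an estimated correlation), with YPEL3 at 1.66 ± 0.20, KLHL24 at 1.28 ± 0.15, CCNG2 at 0.95 ± 0.11 and INSR at 0.78 ± 0.09. TGFβ and BMP genes had 15 of 24 higher and 0 lower (19 adjusted over the list alone; adjusted p = 1.1e-09, and 0.012 with an estimated correlation), led by the inhibitors of differentiation ID2 (0.95 ± 0.08) and ID3 (0.87 ± 0.09) and the inhibitory SMAD7 (0.78 ± 0.09). ID2, ID3 and SMAD7 also rose in WT (0.92 ± 0.09, 1.35 ± 0.08 and 0.67 ± 0.10) and in R (0.44 ± 0.08, 0.47 ± 0.09 and 0.62 ± 0.12). The difference of this list's drug response between KO and WT had a median of 0.20 (camera adjusted p = 0.069, and adjusted p = 0.39 with an estimated correlation). With the clone nested in the line as a replicate block these were 0.032 and 0.42. Of 16 immediate early and heat shock genes 10 rose and 2 fell (13 adjusted over the list alone; adjusted p = 2.6e-10, and 0.041 with an estimated correlation), among them FOSB (1.94 ± 0.17), FOS (1.44 ± 0.13) and EGR1 (1.17 ± 0.07). Readouts of ERK signalling had 11 of 24 higher and 1 lower (14 adjusted over the list alone; adjusted p = 6.0e-07, and 0.041 with an estimated correlation), including the ERK phosphatase DUSP6 (0.82 ± 0.10). With the clone as a replicate block the estimated-correlation adjusted p was 0.003 for the MYC targets and 0.089 for the ERK readouts.

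The metabolic lists also fell in KO: 17 of 28 SREBP targets with 1 higher (21 adjusted over the list alone; adjusted p = 2.4e-08, and adjusted p = 0.25 with an estimated correlation), and 11 of 22 ATF4 targets with 1 higher (15 adjusted over the list alone; adjusted p = 1.6e-05, and adjusted p = 0.19 with an estimated correlation). FASN, the fatty acid synthase, changed by -0.75 ± 0.11 and the glycolytic HK2 by -1.14 ± 0.07. Interferon-stimulated genes had 17 of 31 higher and 0 lower (17 adjusted over the list alone; adjusted p = 2.4e-08, and adjusted p = 0.27 with an estimated correlation). These came from one clone more than the other: in KOD2 alone 27 rose and 0 fell (median 1.05), and in KOB2 alone 7 rose and 8 fell (median 0.08, camera adjusted p = 0.87). Mitochondrially encoded genes had 4 of 13 lower and 0 higher (12 adjusted over the list alone; adjusted p = 3.1e-05, and adjusted p = 0.34 with an estimated correlation). All 13 fell in KOB2 alone and 0 changed in KOD2 alone. The mitochondrial share of counts was 5.90% and 5.40% in untreated KOB2, 4.11% and 2.57% in untreated KOD2, 2.29% and 1.19% in treated KOB2, and 3.45% and 2.66% in treated KOD2. Lysosomal and autophagy genes had 13 of 26 higher and 1 lower (15 adjusted over the list alone; adjusted p = 2.5e-05, and adjusted p = 0.19 with an estimated correlation), among them GABARAPL1 (1.21 ± 0.16) and the protease gene CTSB (0.73 ± 0.11).

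LBH (2.55 ± 0.24), MT2A (2.27 ± 0.26), LY6G6C (2.21 ± 0.26), TMEM37 (2.07 ± 0.25) and the matrix gene TGFBI (2.05 ± 0.20) had the largest rises in KO. CEACAM5 rose by 2.05 ± 0.32, to 94.54 and 85.23 CPM in treated KOB2 and 245.7 and 224.5 CPM in treated KOD2. DMBT1 (-1.78 ± 0.24), the coactivator PPARGC1B (-1.52 ± 0.18), the lipid transporter MFSD2A (-1.52 ± 0.19) and the receptor ROR1 (-1.36 ± 0.23) fell the most. In total 2870 of 13732 genes changed, 1630 higher and 1240 lower, 288 of them at least 2-fold, and 3443 with the clone as a replicate block. The libraries of a clone are not independent clones: with each clone summed to 1 sample per condition, 12 genes passed, and the count was 1751 without untreated KOB2_1 and 1745 without untreated KOB2_2.

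**Figure D3:**
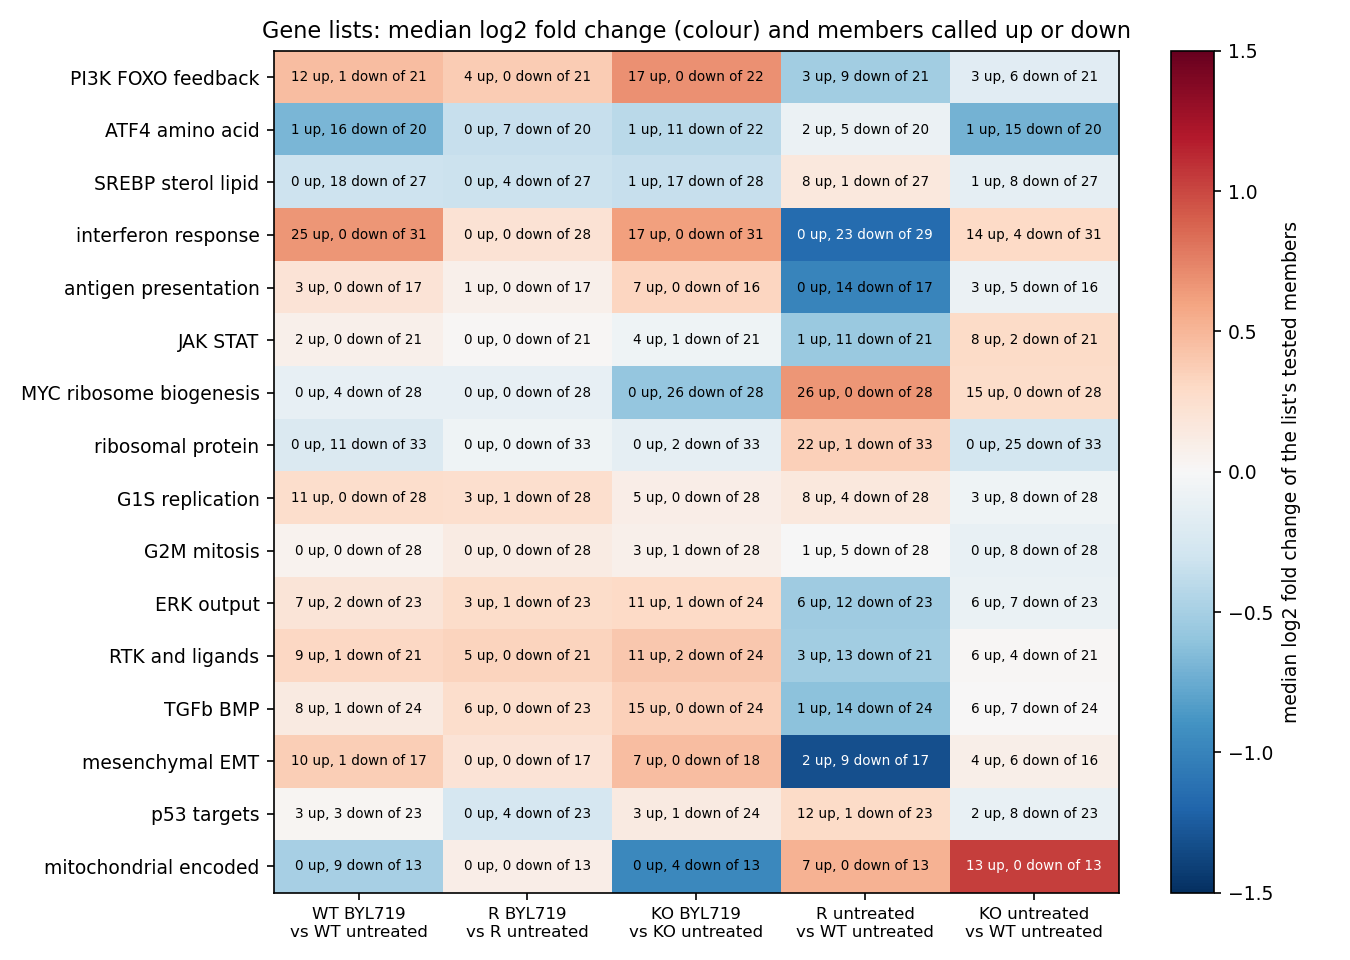
Median log2 fold change (colour) of 16 gene lists (vertical axis) in 5 comparisons (horizontal axis), with the number of members that rose and fell printed in each cell. Interferon-stimulated genes were 25 up and 0 down with the drug in WT, and 0 up and 23 down in untreated R against WT.

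Did the drug act differently in the 3 lines? The difference between responses passed the test for 37 of 14407 genes between R and WT, 6 of 14648 between KO and WT and 18 of 14673 between KO and R. The cystine transporter gene SLC7A11 changed by -1.96 ± 0.18 in WT and 0.21 ± 0.18 in R (difference 2.16 ± 0.27, adjusted p = 0.0035). PCK2, a mitochondrial enzyme of gluconeogenesis, changed by -1.05 ± 0.10 in WT and 0.30 ± 0.10 in R (1.35 ± 0.14, adjusted p = 0.0015). PSAT1 fell in both, by less in R (0.87 ± 0.12, adjusted p = 0.005). The haem-degrading HMOX1 rose by 0.75 ± 0.09 in WT and changed by -0.55 ± 0.12 in R (-1.31 ± 0.15, adjusted p = 0.0015). MDM2 responded by 0.27 ± 0.09 in WT and -0.52 ± 0.06 in R (-0.79 ± 0.11, adjusted p = 0.005). In KO, the cell cycle inhibitor CDKN2B rose by 0.72 ± 0.07, against -0.41 ± 0.09 in WT (1.15 ± 0.10, adjusted p = 3.5e-05), and DUSP6 rose by 0.82 ± 0.10, against -0.18 ± 0.11 (1.02 ± 0.15, adjusted p = 0.023). Of the 6 genes between KO and WT, CDKN2B alone passed whichever library was left out.

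Whole lists were compared in the same way, a test added after the data were seen. The ATF4 targets differed between R and WT with a median difference of 0.38 (camera adjusted p = 1.6e-09, and 0.012 with an estimated correlation, which became adjusted p = 0.087 with the clone nested in the line as a replicate block). Between KO and WT the ATF4 targets differed by 0.40 (adjusted p = 3.5e-04, and adjusted p = 0.39 with an estimated correlation). In the contrast of R and WT, mitochondrially encoded genes differed by 0.60 (adjusted p = 2.3e-08, and adjusted p = 0.29 with an estimated correlation) and p53 targets by -0.20 (adjusted p = 3.9e-07, and adjusted p = 0.074 with an estimated correlation). Interferon-stimulated genes differed there by -0.43 (adjusted p = 6.1e-07, and adjusted p = 0.4 with an estimated correlation). The MYC targets of ribosome biogenesis fell more in KO than in WT by a median of -0.38 (adjusted p = 1.1e-22, and adjusted p = 0.16 with an estimated correlation, or 0.0012 with the clone nested in the line). Between KO and R the p53 targets differed by 0.42 (adjusted p = 5.8e-12, 0.045 with an estimated correlation and 0.0033 with the nested clone) and immediate early and heat shock genes by 0.32 (5.5e-06, 0.045 and 0.016). The NRF2 and detoxification list differed by 0.20 (7.8e-04 and 0.045, and adjusted p = 0.057 with the nested clone), the MYC targets by -0.44 (1.0e-24 and 0.065, and 0.0015 with the nested clone) and the FOXO targets by 0.32 (1.3e-04 and 0.19, and 0.013 with the nested clone). Mitochondrially encoded genes differed by a median of -1.05 between KO and R (adjusted p = 2.5e-07, and adjusted p = 0.3 with an estimated correlation) and of -0.40 between KO and WT (adjusted p = 0.035, and adjusted p = 0.75 with an estimated correlation).

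Single libraries weighed heavily on the numbers of genes whose drug response differed. Between R and WT they were 8 without untreated WT 2 or treated WT 3, 9 without treated WT 1, 13 without untreated WT 1 or treated RC6, 16 without treated WT 2, 18 without untreated RC6, 21 without untreated RD4, 24 without treated RD4 and 66 without untreated RD5. Between KO and WT they were 1 without untreated WT 1, untreated WT 2, treated WT 1 or treated KOD2_1, 2 without treated WT 2 or treated WT 3, 10 without untreated WT 3, 15 without treated KOD2_2, 33 without treated KOB2_1 and 96 without untreated KOD2_2. Between KO and R they were 8 without untreated RD4, 9 without untreated KOB2_1 or KOB2_2, 10 without treated RC6 or RD4, 32 without treated KOB2_1 and 74 without untreated KOD2_2. With the clone nested in the line as a replicate block the counts were 177, 78 and 440, with DESeq2 126, 160 and 250, and with a mean of 50 or more counts 28 between KO and WT and 50 between KO and R.

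How did the resistant clones differ from parental cells before treatment? Interferon-stimulated genes and antigen presentation genes were lower in R and ribosome biogenesis genes higher. Of 29 interferon-stimulated genes 23 fell and 0 rose (23 adjusted over the list alone; adjusted p = 3.9e-12, and adjusted p = 0.15 with an estimated correlation), with the restriction factor BST2 at -4.69 ± 0.30, MX2 at -2.88 ± 0.19 and OAS3 at -2.20 ± 0.16. Of 17 antigen presentation genes 14 fell and 0 rose (16 adjusted over the list alone; adjusted p = 1.5e-10, and adjusted p = 0.13 with an estimated correlation), including the peptidase ERAP2 (-1.46 ± 0.11) and the immunoproteasome subunit PSMB8 (-1.75 ± 0.14). The values of HLA-B (-3.85 ± 0.24) and HLA-F (-4.31 ± 0.29) are uncertain, because HLA genes share reads. Of 28 MYC targets of ribosome biogenesis 26 rose and 0 fell (26 adjusted over the list alone; adjusted p = 3.9e-12, and adjusted p = 0.15 with an estimated correlation), with NOP16 at 0.99 ± 0.11 and MYBBP1A at 0.94 ± 0.08. TGFβ and BMP genes had 14 of 24 lower and 1 higher (18 adjusted over the list alone; adjusted p = 1.2e-09, and adjusted p = 0.13 with an estimated correlation), including the corepressor SKIL (-3.68 ± 0.12) and the BMP receptor BMPR2 (-2.76 ± 0.15). ID1 (-0.37) and TGFBR2 (-0.56) of that list lie in chromosome blocks that were lower as a whole in R. Of 18 NF-κB and chemokine genes 7 rose and 1 fell (8 adjusted over the list alone; adjusted p = 0.0014, and adjusted p = 0.13 with an estimated correlation), with CXCL8 at 2.41 ± 0.36 and CXCL3 at 1.99 ± 0.23.

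Among the largest rises in R were the retinal dehydrogenase ALDH1A1 (8.28 ± 0.42, adjusted p = 4.1e-07), the growth factor IGF1 (6.63 ± 0.55), the transcription factor TCF4 (6.55 ± 0.14, from 4.082 ± 0.238 to 383.3 ± 50 CPM, adjusted p = 1.0e-09) and the secretory protein AGR2 (5.47 ± 0.41). The prostaglandin synthase PTGS2 rose from 5.169 ± 0.808 to 211.4 ± 35.7 CPM (5.36 ± 0.17) and the apolipoprotein APOA2 by 5.38 ± 0.34. Several genes fell to 0 or near it. With 0 counts in all 3 untreated R libraries, the microtubule protein gene MAP1B was at least 772-fold lower, KRT75 at least 543-fold lower and the basal keratin KRT5 at least 245-fold lower, against a floor of 3 counts over the group. GLB1, the lysosomal β-galactosidase (ENSG00000170266, chromosome 3, 32996608 to 33097230), went from 219.8 ± 8.47 to 0.08849 ± 0.0372 CPM (-11.15 ± 0.17, adjusted p = 7.7e-11). GLB1 had 7 counts over all 6 R libraries, so its SE understates the counting error. It lies in a block of chromosome 3 where neighbouring genes were also lower. It overlaps TMPPE, and reads from the shared stretch cannot be assigned with certainty. TMPPE stood at 9.58 CPM in untreated WT and 7.97 in untreated R, far below the level of GLB1 in WT. KRT81 (-9.31 ± 0.24) shares sequence with sister keratins and is uncertain, and FPR3 (-8.50 ± 0.37), DPYSL3 (-7.38 ± 0.21) and the pepsinogen gene PGC (-6.63 ± 0.28) were also among the large falls. In total 5444 of 13713 genes differed, 2551 higher and 2893 lower, and 1601 by at least 2-fold, of which 480 were higher and 1121 lower.

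Neighbouring genes moved together over long stretches in R. Of 154 windows of 20 Mb with 15 or more measured genes, 10 had a median log2 fold change past 1000 shuffles of the genes in untreated R against WT, 6 lower and 4 higher. On chromosome 13 the median over 234 genes was 0.45, with 129 genes higher and 18 lower, and on chromosome 20 it was -0.33 over 380 genes, with 21 higher and 169 lower. In untreated KO the same chromosomes had medians of -0.06 and 0.08. The window of chromosome 3 from 20 to 40 Mb had a median of -0.82 and that of chromosome 6 from 80 to 100 Mb one of -0.78. The 10 windows held 760 of the 13623 genes measured in all 154 windows, and 433 of the 5414 changed genes there, or 8.0%. In KO 2 windows passed, chromosome 18 from 0 to 20 Mb (0.57) and chromosome 1 from 0 to 20 Mb (0.14).

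**Figure D4:**
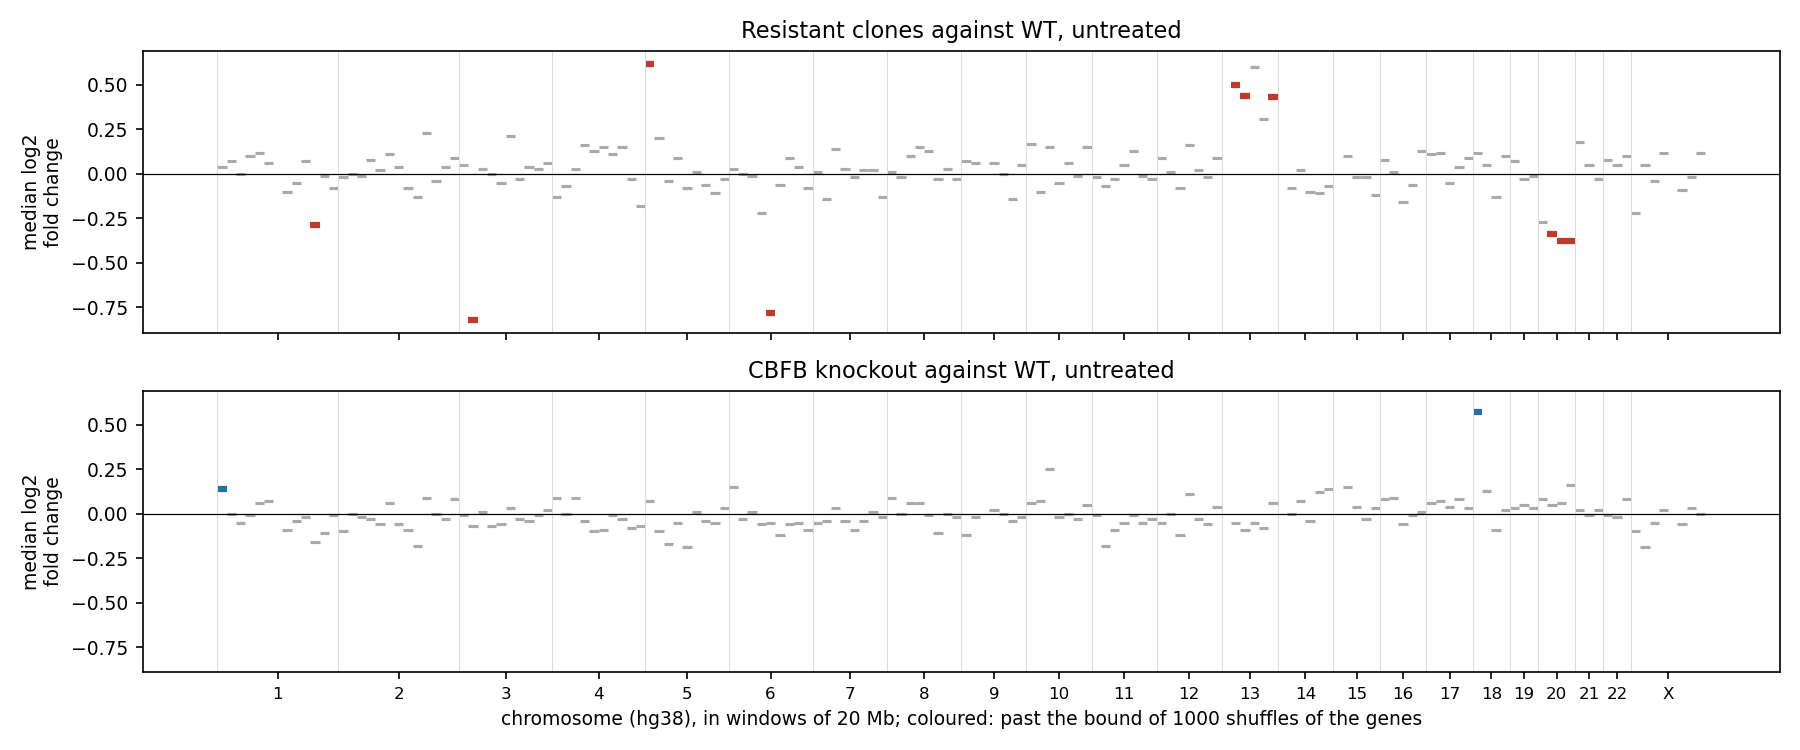
Median log2 fold change (vertical axis) of the genes in each 20 Mb window along the hg38 chromosomes (horizontal axis) for untreated R and untreated KO against untreated WT, with windows past 1000 shuffles coloured. In R the windows of chromosome 13 lie above 0 and those of chromosome 20 below it.

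How did the CBFB knockout clones differ from parental cells without drug? In KO the ATF4 targets were lower and the mitochondrially encoded genes higher. No unedited clone was sequenced, so loss of CBFB cannot be told apart from the origin of the clones. Of 20 ATF4 targets 15 fell and 1 rose (17 adjusted over the list alone; adjusted p = 4.6e-08, and adjusted p = 0.21 with an estimated correlation), with PSPH at -1.27 ± 0.13, PSAT1 at -1.25 ± 0.13 and the proline enzyme PYCR1 at -0.87 ± 0.08. All 13 mitochondrially encoded genes rose (13 adjusted over the list alone; adjusted p = 9.0e-05, and adjusted p = 0.8 with an estimated correlation), with a median of 1.04. In KOB2 alone 13 rose and in KOD2 alone 8, and the mitochondrial share of counts was 2.57% to 5.90% in these KO libraries against 2.13% to 2.40% in WT. Of 33 ribosomal protein genes 25 fell and 0 rose (29 adjusted over the list alone; adjusted p = 9.1e-05, and adjusted p = 0.8 with an estimated correlation). MYC targets of ribosome biogenesis had 15 of 28 higher and 0 lower (17 adjusted over the list alone; adjusted p = 2.5e-04, and adjusted p = 0.8 with an estimated correlation). In KOB2 alone 18 of them rose and in KOD2 alone 5. Interferon-stimulated genes had 14 of 31 higher and 4 lower (20 adjusted over the list alone; adjusted p = 0.022, and adjusted p = 0.8 with an estimated correlation), with 18 higher in KOB2 alone and 7 in KOD2 alone. Among receptors, the hepatocyte growth factor receptor gene MET (1.38 ± 0.11) and PDGFRA (1.60 ± 0.17) were higher and ROR1 (-2.28 ± 0.19) and the ligand GAS6 (-1.14 ± 0.10) lower. That list of 21 had 6 higher and 4 lower (11 adjusted over the list alone, camera adjusted p = 0.92), with a median of 0.02 and a mean of -0.06.

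PRSS35 (5.29 ± 0.53), the receptor EPHB6 (3.35 ± 0.22), APOA2 (2.95 ± 0.34), CCDC80 (2.89 ± 0.28), the hexokinase HKDC1 (2.85 ± 0.13) and CEACAM5 (2.75 ± 0.18) were among the largest rises in KO with a mean of 100 or more counts. IKZF3, a lymphoid transcription factor (2.81 ± 0.71, adjusted p = 0.011), stood at 57.33 and 55.24 CPM in KOB2 and 7.744 and 7.526 CPM in KOD2, and it was not called by limma-voom (adjusted p = 0.12) or without untreated WT 3 (adjusted p = 0.051). KRT5 had 0 counts in the 4 KO libraries and was at least 327-fold lower. FPR3 (-8.09 ± 0.16), the ligand WNT6 (-7.10 ± 0.29), MAP1B (-6.57 ± 0.37), the perforin gene PRF1 (-6.26 ± 0.26) and FGG (-5.83 ± 0.26) also fell, as did KRT81 (-8.61 ± 0.23), with the uncertainty of shared reads. In total 4349 of 13880 genes differed, 1966 higher and 2383 lower, and 939 by at least 2-fold. The count was 2733 with the libraries of each clone summed and 2608 with KOD2 alone.

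Untreated KO and R were then compared directly, 2 derived lines of the same parent. Interferon-stimulated genes were higher in KO, 27 of 31 with 1 lower (28 adjusted over the list alone; adjusted p = 4.8e-15, and adjusted p = 0.18 with an estimated correlation), including BST2 (5.53 ± 0.29). All but 1 of 33 ribosomal protein genes were lower in KO (32 lower, 1 higher, 33 adjusted over the list alone; adjusted p = 1.2e-16, and adjusted p = 0.2 with an estimated correlation). TGFβ and BMP genes had 14 of 24 higher and 2 lower (16 adjusted over the list alone; adjusted p = 1.3e-09, and 0.027 with an estimated correlation), led by SKIL (4.35 ± 0.10) and BMPR2 (2.74 ± 0.07). GLB1 (10.26 ± 0.27), DPYSL3 (8.21 ± 0.20) and PGC (7.27 ± 0.38) were higher in KO, and ALDH1A1 (-9.55 ± 0.47) and TCF4 (-9.14 ± 0.14) lower. NKAIN4, which like GLB1 lies in a block shifted in R, had 3 counts in R and a ratio of 207 (95% counting interval 70.7 to 1010). In total 6345 of 13908 genes differed, 3025 higher and 3320 lower, and 1581 by at least 2-fold.

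Under drug, R kept a low interferon programme relative to WT: 27 of 31 genes were lower and 0 higher (27 adjusted over the list alone; adjusted p = 7.3e-21, and adjusted p = 0.17 with an estimated correlation), with a median of -1.69. Antigen presentation genes had 15 of 17 lower and 0 higher (16 adjusted over the list alone; adjusted p = 1.0e-13, and 0.034 with an estimated correlation), and MYC targets of ribosome biogenesis 27 of 28 higher and 0 lower (27 adjusted over the list alone; adjusted p = 2.4e-13, and adjusted p = 0.12 with an estimated correlation). All 13 mitochondrially encoded genes were higher (13 adjusted over the list alone; adjusted p = 5.9e-07, and adjusted p = 0.34 with an estimated correlation), beside a mitochondrial share of 2.59% to 3.83% in treated R and 1.34% to 2.04% in treated WT. TCF4 (7.10 ± 0.14), SERPINB2 (6.03 ± 0.38) and PTGS2 (5.84 ± 0.19) were higher. ALDH1A1, with 3 counts in treated WT, had a ratio of 1120 (95% counting interval 385 to 5460) and IGF1 one of 379 (129 to 1840). MAP1B was at least 1210-fold lower. In total 6521 of 13800 genes differed between treated R and WT, 3145 higher and 3376 lower, and 1774 by at least 2-fold.

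Treated KO differed less from treated WT, with 2298 of 13877 genes, 1225 higher and 1073 lower, and 665 by at least 2-fold. The PI3K and AKT pathway list had 7 of 25 higher and 1 lower (9 adjusted over the list alone; adjusted p = 0.049, and adjusted p = 0.8 with an estimated correlation), with the regulatory subunits PIK3R3 (1.12 ± 0.20) and PIK3R1 (0.82 ± 0.09) and the kinase SGK1 (0.97 ± 0.11) higher. PRSS35 (4.75 ± 0.22), the dynein DNAH2 (3.24 ± 0.16), HKDC1 (3.12 ± 0.27) and the lipoxygenase ALOX5 (3.09 ± 0.16) were higher, and FPR3 (-8.37 ± 0.16), ADAMTSL2 (-7.47 ± 0.23), KRT5 (-6.61 ± 0.42) and MAP1B (-6.50 ± 0.29) lower. The count was 1424 without treated WT 1, 1512 without treated WT 2 and 1512 without treated WT 3, and it was 3516 with KOD2 alone. Between treated KO and treated R, 6592 of 13945 genes differed, 3492 higher and 3100 lower, and 1959 by at least 2-fold. Interferon-stimulated genes had 29 of 31 higher in KO and 1 lower (30 adjusted over the list alone; adjusted p = 3.5e-11, and adjusted p = 0.32 with an estimated correlation), and MYC targets of ribosome biogenesis 27 of 28 lower and 0 higher (27 adjusted over the list alone; adjusted p = 3.6e-14, and adjusted p = 0.15 with an estimated correlation). PIM1 was higher in treated KO than in treated R by 0.37 ± 0.14 (adjusted p = 0.04), a call that ended without treated RC6 (0.19), treated RD4 (0.15), treated KOD2_1 (0.092) or treated KOD2_2 (0.095).

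The changes shared between lines were counted. Of 13482 genes tested in both untreated comparisons with WT, 1711 differed in the same direction in R and KO, 660 higher and 1051 lower, and 557 in opposite directions. Independent lists of these sizes would share 850.5 in the same direction and 833.8 in opposite ones. Unchanged groups simulated against common, also simulated, WT libraries shared at most 1 gene in 40 draws. With no gene changed almost none is called, so that count cannot show how far common controls enlarge the overlap. Across genes, which are not independent replicates, the 2 sets of log2 fold changes correlated at 0.43, while the simulated groups, which share only their controls, averaged 0.52. The covariance was 0.267 against 0.0157 in the simulation. Both comparisons used the same 3 WT libraries. The effect of common controls was simulated for unchanged genes only and was not removed from these counts. The drug responses overlapped more than independent lists would: WT and KO shared 970 genes in direction with 5 opposite (187.7 expected), WT and R 233 with 3 opposite (26.1 expected), and R and KO 251 with 2 opposite (43.7 expected). In all 3 lines 125 genes rose and 61 fell, among them MT2A, LY6G6C, CEACAM5, MEGF6 and EMP1 upward and SOX2, PSAT1 and PIK3R3 downward. This count across lines was added after the data were seen.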

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

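The 3 patterns weighed here were noticed in the results, with limits of 16-fold and 20 Mb set then, and every test of them except the one without shared WT libraries was chosen after the result was seen.

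In untreated and treated KO, 105 gene and group sets were tested for a library far from its group. Of these, 2 were picked out, where chance alone picks out 1 in 20 (5%) if libraries are independent. The KO libraries are not, as they come in pairs from a clone. WT and R libraries were not tested in this way. CACHD1 in untreated KOB2_2 stood at 15 CPM, the other KO libraries at 10.4 to 11.2. ALDH1A1 in treated KOB2_2 stood at 0.0671 CPM, a single read, the others at 0.

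Differences between drug responses were picked out because they passed the test. Between R and WT these were 37 genes, with PCK2 at 1.35, HMOX1 at -1.31, SLC7A11 at 2.16, MDM2 at -0.79, ID3 at -0.88, PSAT1 at 0.87, CYP1A1 at -1.46, RALGPS1 at -0.78, ABHD6 at -0.83 and ZSCAN31 at -0.86. Between KO and WT these were 6 genes, CDKN2B at 1.15, DUSP6 at 1.02, SCNN1A at 1.29, EPHB6 at -1.72, TMEM37 at 1.99 and SEMA3C at 1.23. Between KO and R these were 18 genes, with ZSCAN31 at 1.25, STT3B at 0.88, TXNDC5 at 1.20, GPX2 at 0.88, HK2 at -0.73, ECE1 at 0.75, HMOX1 at 1.11, JUNB at 0.96, CDKN2B at 0.88 and PHLDB2 at -0.64.

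For these differences the lines' labels were exchanged in 100 labelings and tested by limma. For R and WT the real labels gave 37 genes and the highest other 0 (1 labeling with as many, a share under 0.05). For KO and R the real labels gave 27 and the highest other 87 (2 labelings with as many, a share under 0.05). For KO and WT the real labels gave 5 and the highest other 468 (4 labelings with as many, also under 0.05). The labelings exchange libraries of the same R or KO clone as if they were independent, and with clones as units they are too few for a share under 0.05, so a chance arrangement was not excluded for any of these differences. A labeling with several times the real count points to a structure of the samples beside the difference between lines.

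Among the comparisons of 3 with 3 libraries, the 10 splits were too few for a share under 0.05. The real split gave 1761 genes for the drug in WT, 405 for the drug in R, 5444 for untreated R against WT and 6521 for treated R against WT, the highest other 0 each, with 1 split reaching the real value. With 35 splits of single libraries, 1 reached the real value for the drug in KO (2870, highest other 161), untreated KO against WT (4349, highest other 1546), untreated KO against R (6345, highest other 0), treated KO against WT (2298, highest other 1) and treated KO against R (6592, highest other 0). Those splits treat the KO libraries as exchangeable, but they come in pairs from 2 clones, and with clones as units the splits are too few for a share under 0.05, so a chance arrangement was not excluded there.

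In R, long blocks of neighbouring genes were shifted together, with a median size of 0.44 over 10 blocks. Removing the trend on GC content and gene length left 0.46, and genes with a mean of 100 or more counts gave 0.49. KO against the same WT libraries moved by -0.002 in the direction of R, so the controls do not carry the shift. The shift was kept in 98.3% of library and block pairs (59 of 60), including 29 of 30 under drug. The blocks were chosen in the untreated libraries, so the untreated pairs were likely to keep it by that choice. Any stable difference of the clones would also persist under drug. A different copy number of these blocks in R is a possible explanation that these values do not single out, and DNA would have to test it.

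Of 10543 genes at 5 CPM or more in untreated WT, 14 were at least 16-fold lower in both untreated R and KO. Independent lists would be expected to share 0.17. Among genes at 5 CPM or more in R and KO, 0 were that much higher in both. Only 23 were that much higher in R and 4 in KO, too few for this 0 to show a direction. At 4-fold, 2 genes were higher in both and 49 lower in both. The 14 low genes were KRT81, FPR3, WNT6, MAP1B, KRT75, FGG, FGF20, KRT6A, PRR5L, KRT5, IGFBP5, ADAMTSL2, ANGPT2 and UGT1A6. Of these, the keratins KRT81 and KRT6A and UGT1A6 share reads with sister genes. Between comparisons with no common library, untreated R against WT and treated KO against treated WT, 10 genes were that low (0.14 expected), so an overlap of this kind also arose without shared WT libraries. The called drug responses of the 14 genes in WT spanned 4.02 log2 units. This argues against RNA of a single outside source with a fixed composition. It does not bear on other cells in the WT cultures, which could respond to the drug themselves. In 98.6% of gene and clone pairs (69 of 70) the clone was that low. The genes were chosen by the means of these same untreated libraries, so the pairs were likely to be low by that choice. Without unselected WT clones an origin of R and KO from single parental cells cannot be told apart from other causes.

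Fewer genes were called for the drug in R (405) than in WT or KO. With the clone as a replicate block 3412 were called, so spread between the R clones may account for the low count. Over 3326 genes compared, of 3443 called in KO with the clone as a replicate block, the median response was 0.178 in R and 0.239 in WT, or 74.3%. The ratio was given no spread, and the score from held-out WT libraries put the R response at 58.5 of 100, so the size of the response in R is left open.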

How the results depend on the processing

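The comparisons between lines kept their counts under most settings, and those of the drug in R and of differences between responses did not. For the drug in R, 3412 genes were called with the clone as a replicate block, so spread between the clones may play a part. For the differences the cause was not tested. A fold of 2 or more left 217 genes for the drug in WT, 45 in R and 288 in KO, and between lines 1601 and 1774 for R against WT, 939 and 665 for KO against WT and 1581 and 1959 for KO against R (untreated and treated), and 342 of the changes shared by R and KO. With an estimated correlation 13 list calls were made, against 126. For the drug in R, DESeq2 called 920, no filter 643 and all 6 groups in 1 fit 772, against 405. No filter moved the share of higher calls in WT from 57.0% to 48.9% and in R from 54.1% to 48.7%. For KO, summing the clones gave 12 for the drug and 2733 untreated against WT, and KOD2 alone 2608 untreated and 3516 treated against WT. DESeq2 gave 126, 160 and 250 genes for the differences between R and WT, KO and WT, and KO and R, a mean of 50 or more counts gave 28 for KO and WT and 50 for KO and R, and a difference of 2-fold or more 13 for R and WT and 6 for KO and R.

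In WT, untreated and treated libraries share only a number: deviations of same-numbered libraries correlated at 0.01, -0.00 and -0.13, and no library correlated best with the one of its own number. With that number as a replicate block 1088 genes were called in WT, against 1761. With the clone as a replicate block the drug called 3412 genes in R and 3443 in KO, and the differences were 177 for R and WT, 78 for KO and WT and 440 for KO and R. The clone block also brought CBFB (adjusted p = 0.012), PIM1 (1.8e-06) and PIK3CA (0.049) past the threshold for the drug in R, RUNX1 (0.03) for the drug in KO and PIM1 (0.016) for KO and R, and the number block took PIK3CA (0.079) below it in WT. With each clone's libraries summed, RUNX1 was not called for the drug in KO. For the comparisons between lines within a treatment, no paired analysis was possible because WT, R and KO share no clone.

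With 1 library left out, the drug in WT gave 923 (without treated 3) to 2371 (without untreated 3), in R 21 (without treated RC6) to 383 (without untreated RD5) and in KO 1745 (without untreated KOB2_2) to 2918 (without treated KOB2_1). Treated KO against WT gave 1424 to 2480. Differences gave 8 to 66 for R and WT, 1 to 96 for KO and WT and 8 to 74 for KO and R. R against WT untreated stayed within 4168 to 5846, KO against WT within 3130 to 4769 and KO against R within 5208 to 6422, and treated R against WT and KO against R within 5293 to 7064 and 5224 to 6562. Of the named genes' results without 1 library, 1218 stayed on their side of the threshold, 88 dropped below it and 5 rose past it. Leaving out 1 KO library does not take out its clone. With the libraries of each KO clone summed, 80 of the named results in comparisons with KO stayed on their side and 23 dropped below the threshold. A pseudocount was not varied because the values are counts. List tests with clone blocks, per clone and of differences, and counts across lines, were added after the data were seen. Depth limits genes with few counts, such as RUNX2 and RUNX3.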

Other observations

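Among gastric and intestinal genes the intestinal factor CDX2 rose with the drug in WT (0.98 ± 0.08) and was higher in untreated KO (0.89 ± 0.07) and R (1.25 ± 0.09) than in WT, though in R it lies in a block of chromosome 13 that was higher as a whole. In WT 11 of 23 such genes rose with the drug and 2 fell (14 adjusted over the list alone; camera adjusted p = 7.3e-05, and adjusted p = 0.15 with an estimated correlation), with CDH17 at 0.70 ± 0.08. In untreated KO the hepatocyte factor HNF4A (0.69 ± 0.07) and MUC13 (0.70 ± 0.07) were higher and SOX2 lower (-1.49 ± 0.13), while that list of 23 had 9 higher and 5 lower (15 adjusted over the list alone, camera adjusted p = 0.14). The fibrinogen genes FGA (-3.50 ± 0.18) and FGB (-3.32 ± 0.20) were lower in untreated KO than in WT.

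In untreated KO the receptor NOTCH3 (1.97 ± 0.16) and its ligand JAG1 (1.54 ± 0.13) were higher, and ANKRD1 (-2.41 ± 0.10) and the WNT target SP5 (-1.09 ± 0.09) lower. The list that held them, named for WNT, NOTCH and Hedgehog, had 7 of 22 genes higher and 6 lower (13 adjusted over the list alone, camera adjusted p = 0.96, median -0.08, mean 0.06). The survival gene BCL2 was higher (3.28 ± 0.26) and the pro-apoptotic PMAIP1 (-1.12 ± 0.13) and BBC3 (-0.97 ± 0.12) lower, while the apoptosis list of 26 genes had 6 higher and 8 lower (14 adjusted over the list alone, camera adjusted p = 0.99, median -0.10, mean 0.01). With the drug BBC3 rose in KO by 0.83 ± 0.12 and BMF by 2.00 ± 0.13. In untreated R the Wnt inhibitor NKD1 (-4.12 ± 0.23), the stem cell receptor LGR5 (-1.36 ± 0.08) and BMF (-2.89 ± 0.27) were lower.

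The drug response of WT was made into a score with held-out WT libraries, an idea that came after the data were seen. On a scale where untreated WT is at 0 and treated WT at 100, untreated R stood at -40.8 ± 3.8 and treated R at 17.6 ± 2.5 (n = 3 each, difference 58.5, exact p = 0.1, the smallest possible). Untreated KO stood at 36.8 ± 3.3 and treated KO at 118.0 ± 9.5 (4 libraries each from 2 clones, difference 81.2), and KO exceeded R by 77.6 untreated and by 100.4 treated. Untreated KOB2 stood at 40.4 and 38.4, untreated KOD2 at 35.5 and 32.9, treated KOB2 at 108.9 and 111.0 and treated KOD2 at 128.3 and 123.8. No p is given for KO because libraries of the same clone are not independent replicates.

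The authors' deposited calls numbered 1763 for the drug in WT, 904 in R and 3078 in KO, and 1616, 403 and 2806 of them had a call in the same direction here. For untreated R against WT the numbers were 5219 and 4948, and for untreated KO against WT 4208 and 3992. Of GLB1's neighbours in R, STT3B (-1.33), CRTAP (-1.18) and CMTM6 (-1.26) were lower, and TMPPE, which overlaps it, stood at -0.26.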
